A study of Mus musculus with 6 samples.

How the data were processed

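The data are read counts per gene for 6 mRNA sequencing libraries of the mouse CAD line, 3 from undifferentiated cells and 3 from cells kept for 5 days in 100 µM dexamethasone with 1% serum in place of 8%. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with a phenol-based reagent, libraries were made from 500 ng of total RNA with an mRNA selection kit and 12 cycles of amplification, and 75-base reads were sequenced on a NextSeq. Per the submitters' processing notes, the tools included FastQC 0.11.9, Trim Galore 0.6.4, HISAT2 2.2.0, Subread 1.6.4 and DESeq2, and the genome build was GRCm38.p6; the notes as used here do not give each tool's role. Per the file headers, the authors counted reads with featureCounts 1.6.4 over exons grouped by gene of Ensembl release 96, with the strand setting 1 and no option to count reads that align to several places or overlap several genes. Reads shared between near-identical genes were therefore not counted or went to the copy they matched best, which makes values of paralogs, multigene families and pseudogenes uncertain. The deposited values are raw whole-number counts, and no normalization had been applied to them. One file was given per library, so no replicates were pooled.

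The 55536 gene identifiers of the files were matched to GENCODE M21, which is built on the same release; all 55536 had a name there and the same start and end. Coordinates are those of GRCm38, counted from 1. The counts summed to between 6411105 and 8757992 per library, at which 3 reads in a library correspond to between 0.327 and 0.487 CPM. Genes were kept by edgeR's filterByExpr, with a minimum count of 10 and a minimum total of 15; the 12664 genes kept held 99.8% of all counted reads. Libraries were scaled with TMM factors and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) in a design with the group as the only term; genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The common biological coefficient of variation was 4.41%. Means and SDs of CPM were computed from TMM-scaled libraries. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Where a group had no read, a lower bound of the fold was computed against 3 reads over the group, and with 1 to 3 reads the ratio of scaled reads was given with its exact 95% binomial interval.

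Gene lists for steroid response, catecholaminergic and neuronal functions, cell division, metabolism, stress and other cell types, 40 in all, the rule for named genes, the design and all alternatives but the last 2 were fixed before the data were examined. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with camera at an estimated correlation and with fry, each adjusted over the 37 lists. fry tests whether a list's genes move on balance in a direction and does not compare them with other genes. The genes named in the text were chosen by a fixed rule. It took 21 genes of steroid response, catecholamine synthesis, neurites and cell division. It added the 10 largest rises and the 10 largest falls among called genes with an official symbol, a mean of at least 5 CPM in a group and groups that do not overlap. It added up to 2 called members per direction and list with the smallest adjusted p and a mean of at least 1 CPM. Of the genes this rule named, 2 are not reported here. Slc18a1 and the genes of the closing section that fall outside this rule were chosen after their values were seen.

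The test was run on simulated data for the same comparison, with 200 of the 12664 genes changed. In the simulated counts 11975 genes passed the filter. The test recovered 50.0% of genes changed 1.25-fold, 66.0% of those changed 1.5-fold, 84.0% of those changed 2-fold and 100% of those changed 4-fold. Changed genes that failed the filter count as not recovered in these rates. Of its 159 calls, 5.66% were unchanged genes. A planted list was called and 0 of 39 unchanged lists were. In the data themselves 9997 of 12664 tested genes (78.9%) were called, a far larger share than the simulation changed. These rates hold for the simulated setting and were not measured at such a share. Libraries of a group differed by more than sampling noise (chi-square per degree of freedom 1.65 to 3.19 over genes with at least 20 reads), so no library was counted as a copy of another.

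The alternatives were RLE and upper quartile factors, library totals alone, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom, robust dispersion, each library left out in turn, the replicate number as a block, an offset for gene length with and without that block, mitochondrial and ribosomal protein genes left out, protein-coding genes alone, a test against a fold of 2 and an adjusted p under 0.01. An offset for the GC content of the annotated transcripts and a run without processed pseudogenes were added after the data had been seen. Processed pseudogenes were matched to protein-coding transcripts with blastn 2.17.0 (at least 80% identity over at least 50% of the pseudogene). No sample was left out.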

Results

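Gene expression was measured by sequencing of mRNA libraries from CAD cells, a mouse catecholaminergic line of the central nervous system transformed with simian virus 40. Proliferating, undifferentiated cells were compared with cells differentiated by dexamethasone, a synthetic glucocorticoid. Each group had 3 libraries. The undifferentiated cells grew in medium with 8% serum. The differentiated cells received 100 µM dexamethasone for 5 days in medium with 1% serum, so the steroid and the lower serum differed together between the groups and every difference given here is of that combination. The deposited counts summed to 7414047, 8168939 and 6476847 reads in undifferentiated replicates 1, 2 and 3. They summed to 8751906, 8757992 and 6411105 reads in dexamethasone replicates 1, 2 and 3. The labels call the samples of a group independent but do not say whether they came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Mitochondrial transcripts took 3.17% ± 0.212 (SD, n = 3) of counts in undifferentiated and 3.17% ± 0.247 (SD, n = 3) in differentiated cells. The share of the mitochondrial ribosomal RNAs was 0.0767% ± 0.0127 (SD, n = 3) in undifferentiated and 0.225% ± 0.0259 (SD, n = 3) in differentiated cells. With 3 libraries against 3, an exact permutation test of such a share cannot give a two-sided p under 0.1.

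The comparison asked how the transcriptome of dexamethasone-differentiated CAD cells differs from that of undifferentiated cells. Genes of DNA replication and mitosis fell to a small fraction of their level, genes that the glucocorticoid receptor is known to induce rose, and genes of dense-core vesicles and lysosomes rose. Dbh, which makes noradrenaline from dopamine, fell 13.2-fold, while Th, which catalyses the rate-limiting step of catecholamine synthesis, rose 2.09-fold. Of 12664 genes tested with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 5106 (40.3%) were higher and 4891 (38.6%) lower in differentiated cells. TMM scaling takes most genes to be unchanged, which is in doubt with 78.9% of genes called. Higher and lower, above all for small folds, are therefore relative to the counted mRNA of a library. Changes per cell were not measured. A fitted change of at least 2-fold was found for 2250 of the higher and 1546 of the lower genes; 36 and 1 of these had no read in the lower group, so their fitted folds depend on the prior count. In 5195 genes (41.0%) every differentiated library lay above every undifferentiated library, and in 4922 (38.9%) below, where chance gives 10% for both together. The first principal component held 93.2% of the variance of the log2 CPM values and separated the groups. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.9915 to 0.9932 for libraries within a group and 0.8575 to 0.8634 between groups.

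**Figure D1:**
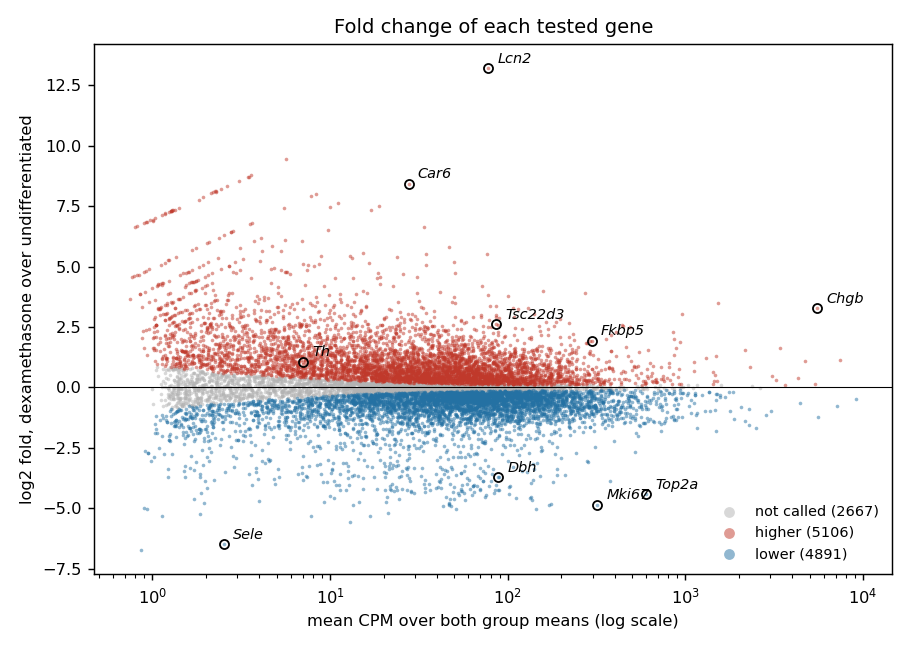
Fitted log2 fold change (differentiated over undifferentiated, vertical axis) against the mean CPM of both groups (horizontal axis, log scale) for each of the 12664 tested genes, with 5106 called higher in red, 4891 called lower in blue and the rest in grey. Named genes are circled; the lines of points at the upper left are genes with few or no reads in undifferentiated cells, whose fitted folds depend on the prior count.

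The cell division genes moved furthest as a group. All 40 tested members of the DNA replication list fell (40 adjusted over the list alone), with a median log2 fold change of -2.75 (camera adjusted p = 2.1e-61, and 0.047 with an estimated correlation). All 38 tested members of the mitosis list fell (38 adjusted over the list alone), with a median of -4.30, a 19.7-fold drop (camera adjusted p = 3.75e-102, and 0.038 with an estimated correlation). Mki67, a marker of cycling cells (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361 in GRCm38), went from 618 ± 22.0 CPM to 21.3 ± 2.74 CPM (SD, n = 3), a log2 fold change of -4.86 ± 0.071 (SE; edgeR adjusted p = 1.69e-27). Top2a, the topoisomerase that untangles replicated DNA (ENSMUSG00000020914, chromosome 11, 98992943 to 99024189), went from 1147 ± 38.3 CPM to 53.5 ± 5.27 CPM (SD, n = 3). Rrm2, a subunit of ribonucleotide reductase, fell 32.2-fold, Mcm5 of the replicative helicase 28.0-fold and Ccna2, cyclin A2, 29.4-fold. Ccnd1, cyclin D1, fell only 1.37-fold, from 290 ± 4.44 to 212 ± 7.20 CPM (SD, n = 3).

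Of 21 tested genes on the list of cell cycle exit, 11 rose and 8 fell (11 and 8 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0797). Cdkn1a, which encodes the inhibitor p21, rose from 21.5 ± 1.38 to 83.9 ± 6.83 CPM (SD, n = 3). Txnip, an inhibitor of thioredoxin and glucose uptake, rose 26.5-fold, and Pik3ip1, an inhibitor of phosphoinositide 3-kinase, 18.3-fold. Cdkn2c and Rbl1 fell 3.34-fold and 3.69-fold. Cdkn1c was at 1.26 ± 0.937 and 2.08 ± 0.891 CPM (SD, n = 3) and was not called (log2 fold change 0.82 ± 0.434 SE, edgeR adjusted p = 0.0845); without undifferentiated replicate 3 it was called (log2 fold change 1.38, edgeR adjusted p = 0.0193), and over all alternatives its adjusted p ranged from 0.0193 to 0.532.

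Targets of the glucocorticoid receptor rose. Of 25 tested members of that list 22 rose and none fell (22 and 0 adjusted over the list alone), with a median log2 fold change of 1.86, or 3.63-fold (camera adjusted p = 1.01e-11, and 0.034 with an estimated correlation). Lcn2, a member, had no read in undifferentiated cells. Set at its lower bound of 1090-fold it still lay above the median, so the median had to stay at 1.86. Fkbp5, a cochaperone of the receptor (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), rose from 123 ± 2.68 to 470.4 ± 5.08 CPM (SD, n = 3; log2 fold change 1.93 ± 0.051 SE, edgeR adjusted p = 1.41e-22). Tsc22d3, known as GILZ (ENSMUSG00000031431, chromosome X, 140539528 to 140600659), rose from 24.0 ± 0.678 to 148 ± 9.19 CPM (SD, n = 3; log2 fold change 2.62 ± 0.073 SE). Ddit4, an inhibitor of mTORC1 signalling, rose 4.53-fold and the clock gene Per1 2.29-fold. The receptor gene Nr3c1 itself (ENSMUSG00000024431, chromosome 18, 39410545 to 39519421) fell from 50.6 ± 5.89 to 37.9 ± 2.28 CPM (SD, n = 3; log2 fold change -0.40 ± 0.084 SE, edgeR adjusted p = 9.85e-05). On the list of the receptor's partners, which includes Nr3c1, 2 of 11 tested genes rose and 5 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.154). The chaperones Hsp90aa1 and Fkbp4 fell 2.59-fold and 2.14-fold, and the coactivators Ncoa1 and Ncoa2 rose 1.75-fold and 1.54-fold.

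The largest rises and falls among genes with at least 5 CPM in a group often began or ended near 0. Lcn2, the secreted protein lipocalin 2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), had no read in undifferentiated cells and 155 ± 7.65 CPM (SD, n = 3) in differentiated cells, at least 1090-fold higher against a floor of 3 reads over the group. On the same floor Synpr, a synaptic vesicle protein, was at least 81.8-fold higher, Acox2 at least 51.3-fold, Dennd2d at least 48.2-fold, Fa2h at least 47.4-fold, G0s2 at least 43.1-fold and Pdzk1ip1 at least 36.7-fold. Car6, a secreted carbonic anhydrase, was counted 386-fold higher (95% counting interval 132 to 1870), Gpr85 349-fold higher (62.2 to 13800) and Hif3a 331-fold higher (59.0 to 13100). Sele, which encodes E-selectin, was counted 125-fold lower (22.0 to 5000). Galnt5, a glycosyltransferase, had 25.5 ± 2.25 CPM in undifferentiated and 0.478 ± 0.569 CPM (SD, n = 3) in differentiated cells. The other genes among the 10 largest falls were Depdc1a, Lrr1, Spc24, Mybl2, Rrm2, Pclaf, Knl1 and Ccna2, with log2 fold changes from -5.34 to -4.88. Leaving out the library that held most of the few reads moved the fitted log2 fold change of Car6 from 8.44 to 11.72 (without undifferentiated replicate 2), of Hif3a from 7.94 to 9.90 (the same library) and of Gpr85 from 8.03 to 10.05 (without undifferentiated replicate 3). It moved that of Sele from -6.48 to -8.22 and of Galnt5 from -5.57 to -6.95 (both without dexamethasone replicate 1).

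Genes of catecholamine synthesis and transport moved both ways, and the list was not called (camera adjusted p = 0.684). Of 12 tested members 7 rose and 4 fell (7 and 4 adjusted over the list alone). Their median log2 fold change was 0.48 and the direction of the test was up, while their mean was -0.04. Th (ENSMUSG00000000214, chromosome 7, 142892752 to 142931128) rose from 4.60 ± 0.674 to 9.52 ± 1.05 CPM (SD, n = 3; log2 fold change 1.06 ± 0.185 SE, edgeR adjusted p = 9.5e-06). Gch1, which makes the cofactor of tyrosine hydroxylase, rose 2.80-fold and Cyb561, a cytochrome of chromaffin granules, 3.00-fold. Dbh (ENSMUSG00000000889, chromosome 2, 27165233 to 27183200) fell from 165 ± 3.07 to 12.5 ± 0.354 CPM (SD, n = 3; log2 fold change -3.72 ± 0.074 SE, edgeR adjusted p = 5.49e-25). Ddc, the decarboxylase that makes dopamine (ENSMUSG00000020182, chromosome 11, 11814101 to 11898144), fell from 3.61 ± 0.188 to 0.466 ± 0.185 CPM (SD, n = 3; log2 fold change -2.86 ± 0.361 SE). Reads were too few to test the noradrenaline transporter gene Slc6a2 (0 reads in each group), the vesicular transporter gene Slc18a2 (3 and 4 reads over undifferentiated and differentiated libraries) and Pnmt, which makes adrenaline (0 and 7 reads). Slc18a1, the other vesicular transporter gene of this list, was tested and rose (log2 fold change 1.33, edgeR adjusted p = 7.01e-13). Of 12 tested transcription factors of noradrenergic and dopaminergic neurons 2 rose and 8 fell (2 and 8 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0797). Gata2 fell 2.23-fold, from 360.0 ± 2.31 to 162 ± 11.7 CPM (SD, n = 3).

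**Figure D2:**
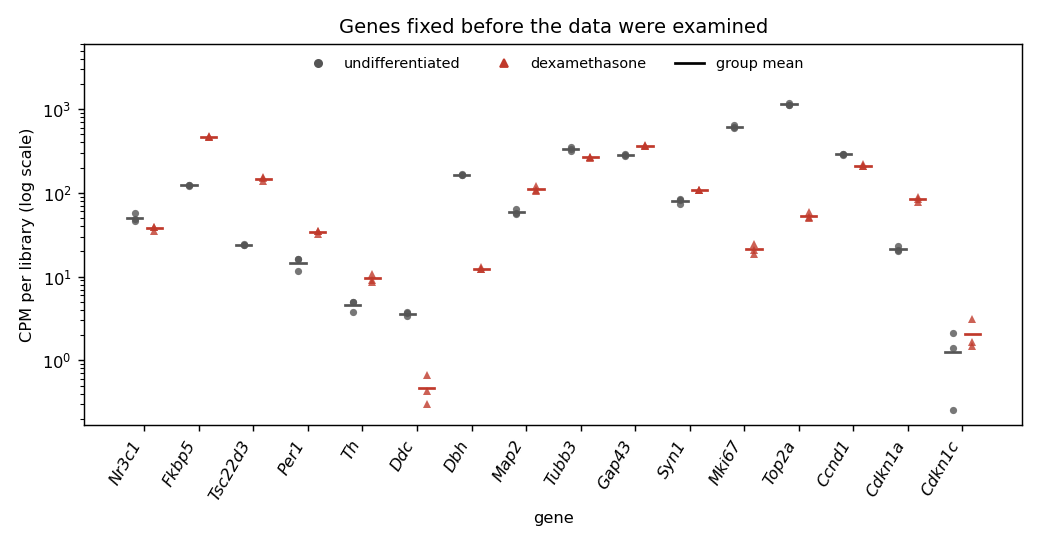
CPM of each library on a log scale for the fixed genes of steroid response, catecholamine synthesis, neurites and cell division that were tested and are reported here, with undifferentiated libraries as grey circles, dexamethasone libraries as red triangles and group means as bars (n = 3 per group). The groups do not overlap for any gene shown except Cdkn1c.

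Genes of secretory vesicles rose. On the dense-core vesicle and neuropeptide list 10 of 12 tested genes rose and 1 fell (10 and 1 adjusted over the list alone), with a median log2 fold change of 1.52 (camera adjusted p = 4.62e-10, and 0.034 with an estimated correlation). Chgb, a granin of the vesicle core (ENSMUSG00000027350, chromosome 2, 132781278 to 132795079), rose from 1028 ± 46.7 to 10000 ± 1124 CPM (SD, n = 3; log2 fold change 3.28 ± 0.065 SE, edgeR adjusted p = 4.09e-25). Scg2, another granin, rose 8.12-fold, and the neuropeptide gene Cartpt fell 2.04-fold. On the synaptic vesicle and release list 20 of 23 tested genes rose and 2 fell (20 and 2 adjusted over the list alone; median 0.86, camera adjusted p = 1.41e-05; adjusted p = 0.14 with an estimated correlation). The calcium sensor genes Syt4 and Syt1 rose 5.86-fold and 2.69-fold and Syn1 1.35-fold, while Cplx1 and Stx1a of the fusion machinery fell 2.22-fold and 1.57-fold.

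On the neurite cytoskeleton list 18 of 25 tested genes rose and 5 fell (18 and 5 adjusted over the list alone; median 0.66, camera adjusted p = 0.00229; adjusted p = 0.17 with an estimated correlation). The axonal kinesin gene Kif1a rose 5.32-fold, Stmn2 2.75-fold, Map2 1.90-fold and Gap43 1.29-fold. Nefh and Tubb3, both neuronal cytoskeletal genes, fell 1.31-fold and 1.25-fold, and Nefl had too few reads to test (5 and 1). On the neural progenitor list 10 of 15 tested genes fell and 4 rose (10 and 4 adjusted over the list alone; median -0.92, camera adjusted p = 0.00947; adjusted p = 0.19 with an estimated correlation). Id2 and Id3, inhibitors of differentiation, fell 18.6-fold and 28.9-fold, while Prom1 rose 5.37-fold. Of 24 tested voltage-gated channel genes 20 rose and 3 fell (20 and 3 adjusted over the list alone), but the list missed the threshold (camera adjusted p = 0.0531; 0.0495 without undifferentiated replicate 2, and 9.3e-06 to 0.19 over all alternatives). Cacna1b, a calcium channel of nerve terminals, rose 4.58-fold, and the potassium channel gene Kcnq3 fell 2.33-fold. The lists of neuronal adhesion and axon guidance (12 of 18 higher, 3 lower; camera adjusted p = 0.0797), neurotransmitter receptors (9 of 13 higher, 2 lower; 0.152) and neurotrophin and GDNF signalling (7 of 12 higher, 3 lower; 0.271) were not called, with the same counts adjusted over the list alone.

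Markers of other cell types were looked at beside these neuronal lists. Of 9 tested fibroblast and mesenchymal markers 6 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.267), among them Fn1, fibronectin, which rose 4.03-fold, and Fbln1, which fell 3.84-fold. Of 5 oligodendrocyte and Schwann cell markers 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.421). Of 4 tested astrocyte markers 2 rose, Aldoc by 11.9-fold and Fgfr3 by 1.80-fold. The endothelial, microglial and blood list left 1 tested gene, Pecam1, which rose 1.69-fold, and the list of other transmitter identities left 2, of which Slc17a7, a vesicular glutamate transporter, rose from 0.384 ± 0.102 to 17.4 ± 0.874 CPM (SD, n = 3). Counts adjusted over the list alone were the same for these last 3 lists, which were too short for a list test.

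Genes of autophagy and lysosomes rose. On the autophagy and lysosome list 30 of 32 tested genes rose and 1 fell (30 and 1 adjusted over the list alone; median 1.27, camera adjusted p = 7.61e-17, and 0.034 with an estimated correlation). The protease gene Ctsl rose from 148 ± 6.32 to 829 ± 17.2 CPM (SD, n = 3) and Grn, progranulin, 6.62-fold. On the cholesterol synthesis list 20 of 23 tested genes rose and 1 fell (20 and 1 adjusted over the list alone; median 1.02, camera adjusted p = 1.58e-07; adjusted p = 0.19 with an estimated correlation), with Msmo1 4.61-fold and Cyp51 3.58-fold higher. On the fatty acid list 17 of 22 tested genes rose and 2 fell (17 and 2 adjusted over the list alone; median 0.73, camera adjusted p = 8e-05; adjusted p = 0.19 with an estimated correlation). Plin2, which coats lipid droplets, rose 6.32-fold and the desaturase gene Scd1 4.92-fold. All 30 tested ribosome biogenesis genes fell (30 adjusted over the list alone; median -1.14, camera adjusted p = 7.87e-15; adjusted p = 0.13 with an estimated correlation), with the nucleolar genes Fbl and Ncl 3.68-fold and 2.91-fold lower. Of 32 tested nuclear genes of the respiratory chain 31 fell and none rose (31 and 0 adjusted over the list alone; median -0.66, camera adjusted p = 1.01e-05; adjusted p = 0.12 with an estimated correlation), Sdhd by 2.32-fold and Atp5b by 1.98-fold.

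Cytosolic ribosomal protein genes fell in 24 and rose in 7 of 44 cases (24 and 7 adjusted over the list alone), and the list was not called (camera adjusted p = 0.169). With library totals only, 16 of these genes fell and 10 rose. Their reads can be split with near-identical processed pseudogenes, so single values such as the 2.21-fold drop of Rps2 are uncertain. Mitochondrially encoded genes of the respiratory chain rose in 4 and fell in 5 of 10 tested cases (4 and 5 adjusted over the list alone; camera adjusted p = 0.955), with a median of -0.28, a mean of -0.04 and a test direction of up. mt-Nd2 rose 2.14-fold and mt-Co1 fell 2.32-fold, in libraries whose mitochondrial ribosomal RNA share also differed (0.0767% and 0.225%). Glycolysis genes rose in 9 and fell in 13 of 24 cases (9 and 13 adjusted over the list alone; camera adjusted p = 0.648), with a median of -0.12 that was 0.00 with library totals only, a mean of 0.08 and a test direction of down. Ldha, lactate dehydrogenase A, fell 3.52-fold and Eno1 2.42-fold, while the neuronal enolase gene Eno2 rose 4.36-fold. Ldha, Eno1 and the nucleolar gene Fbl also have near-identical processed pseudogenes, and mitochondrial genes have copies in the nuclear genome, so these values are uncertain too.

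The lists of heat shock, interferon response, p53 targets and the circadian clock were called with camera's preset correlation, and each lost its call with an estimated one. On the heat shock list 10 of 12 tested genes fell and 2 rose (10 and 2 adjusted over the list alone; median -0.94, camera adjusted p = 9.56e-05; adjusted p = 0.13 with an estimated correlation). The chaperone gene Hsph1 fell from 864 ± 12.8 to 216 ± 3.96 CPM (SD, n = 3), while Cryab, a small heat shock protein gene of few reads, was counted 16.6-fold higher (95% counting interval 5.42 to 83.0; fitted log2 fold change 3.91, and 4.77 without undifferentiated replicate 1). All 17 tested interferon-response genes rose (17 adjusted over the list alone; median 1.57, camera adjusted p = 0.000315; adjusted p = 0.19 with an estimated correlation). Ifi27 rose 6.20-fold and H2-D1 3.41-fold; H2-D1 is a class I histocompatibility gene whose reads can be split with near-identical copies, so its value is uncertain. On the p53 target list 10 of 15 tested genes rose and 3 fell (10 and 4 adjusted over the list alone; median 0.95, camera adjusted p = 0.0114; adjusted p = 0.14 with an estimated correlation). Trp53inp1, which takes part in autophagy and apoptosis, rose 45.5-fold, and the proapoptotic gene Bax fell 1.67-fold. The p53 list was also just short of the threshold with limma voom (adjusted p = 0.0503; 1.5e-05 to 0.14 over all alternatives). On the circadian clock list 12 of 18 tested genes rose and 4 fell (12 and 4 adjusted over the list alone; median 1.19, camera adjusted p = 0.0251; adjusted p = 0.24 with an estimated correlation). The transcriptional repressor gene Bhlhe41 rose 10.1-fold and Arntl, which encodes BMAL1, 2.45-fold, while Nr1d2 fell 2.14-fold.

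**Figure D3:**
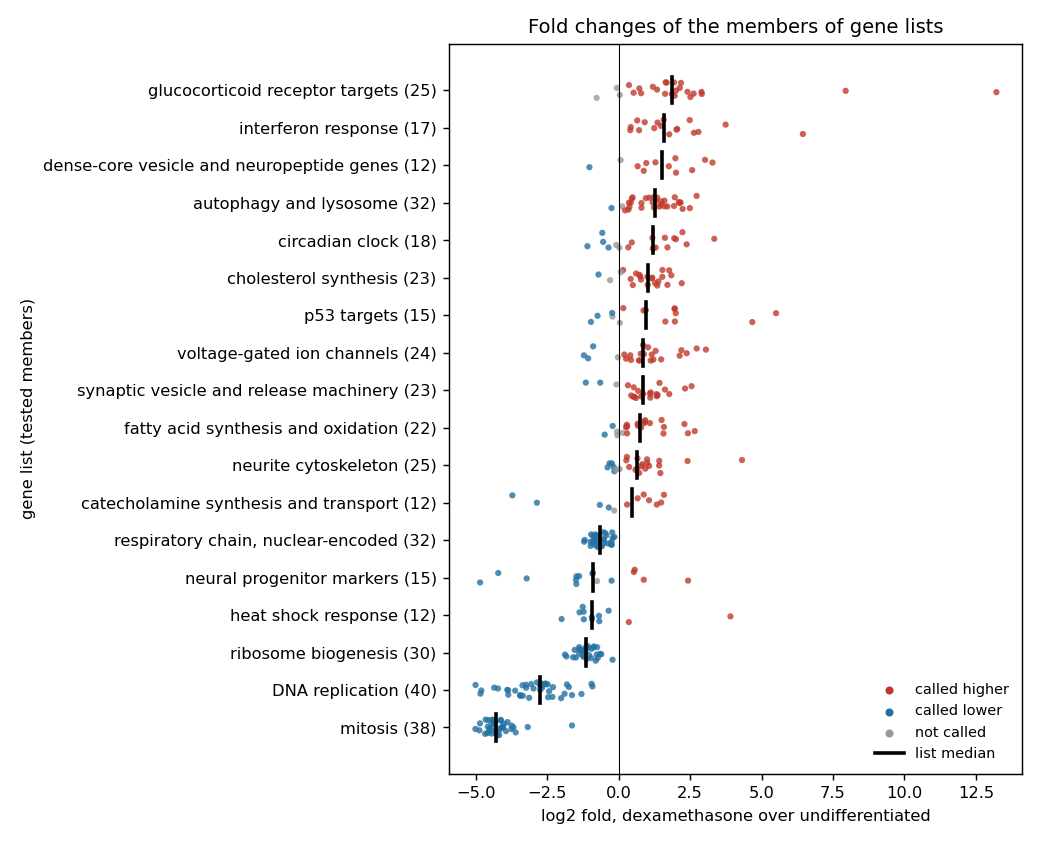
Fitted log2 fold change of each tested member (points, horizontal axis) for the 16 called lists and for the voltage-gated channel and catecholamine lists, which were not called; red members were called higher, blue lower, grey not called, and black bars are list medians. The mitosis and DNA replication members lie wholly below 0, and the point farthest to the right is Lcn2, whose fitted value depends on the prior count because it had no read in undifferentiated cells.

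The other lists were not called. The unfolded protein response list had 12 of 26 tested genes higher and 13 lower (12 and 14 adjusted over the list alone; camera adjusted p = 0.249), with a median of -0.18, a mean of 0.38 and a test direction of up. Ddit3 and Trib3, a transcription factor and a pseudokinase induced by ATF4, rose 13.7-fold and 8.26-fold, while the endoplasmic reticulum chaperone genes Hsp90b1 and Creld2 fell 2.29-fold and 3.44-fold. Serum-response immediate early genes rose in 11 and fell in 10 of 21 cases (11 and 10 adjusted over the list alone; camera adjusted p = 0.644), with a median of 0.16, a mean of -0.09 and a test direction of up. Egr1 fell 2.76-fold and Dusp6 rose 2.78-fold. For the remaining lists the counts were the same when adjusted over the list alone. Among extracellular matrix genes 10 of 19 rose and 8 fell (camera adjusted p = 0.529), with Timp2 5.81-fold higher and Lamc1 2.66-fold lower. Among integrin and focal adhesion genes 15 of 26 rose and 9 fell (camera adjusted p = 0.213), with Itga2 19.4-fold higher and Flna 2.10-fold lower. Among hypoxia-response genes 10 of 16 rose and 6 fell (camera adjusted p = 0.0797), with Vegfa 2.71-fold higher. Among oxidative stress genes 8 of 23 rose and 11 fell (camera adjusted p = 0.729; median -0.14, mean 0.01, test direction down), with Slc7a11 5.97-fold higher and Txn1 3.11-fold lower. Among apoptosis regulators 13 of 20 rose and 7 fell (camera adjusted p = 0.250), with Hrk 3.67-fold higher and Bak1 2.63-fold lower. Among inflammation and NF-kB targets 9 of 11 rose and 2 fell (camera adjusted p = 0.274), with Il6 7.29-fold higher and Nfkb1 1.63-fold lower.

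Of 37 lists with at least 5 tested genes, 16 were called with camera's preset correlation, 10 up and 6 down. With an estimated correlation 5 of them held: the glucocorticoid receptor targets, the dense-core vesicle genes, the autophagy and lysosome genes, mitosis and DNA replication. For p53 targets the estimate was -0.031, below the preset 0.01, so a larger correlation of its own genes does not account for its lost call. The dense-core vesicle list, at -0.058, also went from a camera adjusted p of 4.62e-10 to 0.034. The other lists that lost their call had estimates above the preset, from 0.035 to 0.304. A lost call alone therefore does not show that a list's genes are correlated. Intervals and floors given here cover counting error only, since reads without molecular identifiers are not independent molecules.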

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

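The GC offset and the run without processed pseudogenes were chosen after the data had been seen; all other alternatives were planned. Each of the counts of higher, lower and at least 2-fold changed genes stayed within 1.5 times its value under every alternative run, between 4706 and 5802 higher and 4207 and 5214 lower genes, and between 1684 and 2954 at least 2-fold higher and 1130 and 1832 at least 2-fold lower genes. Without any library in turn, 5022 to 5103 genes were higher, 4674 to 4845 lower, 2286 to 2426 at least 2-fold higher and 1566 to 1623 at least 2-fold lower, and 16 or 17 lists were called. The share of higher genes among the calls went from 51.1% to 56.8% with upper quartile factors and 58.0% with library totals only. It fell below that of lower genes with the length offset (48.6%; 4884 higher, 5158 lower), the length offset with the replicate block (48.6%; 4792 and 5075) and the GC offset (48.9%; 4983 and 5214), so which direction had more calls depends on these settings. Upper quartile factors and library totals moved the median log2 fold change of all genes from 0.02 to 0.12 and 0.14, so changes under these are relative to that shift. With library totals only, some lists had fewer lower members. The count went from 24 to 16 for cytosolic ribosomal proteins, from 6 to 3 for hypoxia response, from 7 to 4 for apoptosis regulators and from 5 to 3 for neurite cytoskeleton. That of mitosis stayed at 38. No label says that the replicate numbers pair the samples. Deviations of same-numbered libraries from their group means correlated at -0.095, 0.036 and -0.071, and not every library correlated best with its own number. These values show no clear effect shared by replicate number, but cannot tell whether same-numbered samples were handled together. With the replicate block, 5017 genes were higher and 4803 lower, 2252 and 1551 by at least 2-fold, and 16 lists were called. The mitochondrially encoded and ribosomal protein lists had no value in the run without these genes.

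Called lists went from 16 to 35 with fry and to 5 with an estimated correlation. There a larger correlation cannot explain the lost p53 call. Other causes of changes were not tested. With the estimated correlation these lists lost their call (adjusted p of each list in parentheses, here and below): ribosome biogenesis (0.13), cholesterol synthesis (0.19), nuclear respiratory chain (0.12), synaptic vesicle (0.14), fatty acid (0.19), heat shock (0.13), interferon response (0.19), neurite cytoskeleton (0.17), neural progenitor (0.19), p53 targets (0.14) and circadian clock (0.24). With fry these gained one: voltage-gated channels (9.3e-06), hypoxia response, cell cycle exit and neuronal adhesion (3.5e-05 each), noradrenergic transcription factors (5.5e-05), neurotransmitter receptors (0.00015), receptor partners (7.8e-05), ribosomal proteins (0.00095), integrins (2.8e-05), unfolded protein response (0.0013), apoptosis regulators (6.5e-05), fibroblast markers (7.8e-05), neurotrophin signalling (1e-04), NF-kB targets (0.00034), oligodendrocyte markers (0.00055), extracellular matrix (0.022), glycolysis (0.0047), catecholamine synthesis (0.017) and oxidative stress (0.0073). Without a filter the lists of voltage-gated channels (0.0136), hypoxia response (0.0186), cell cycle exit (0.0146), neuronal adhesion (0.0383) and noradrenergic transcription factors (0.0476) were called. With limma voom the p53 list was lost (0.0503) and the voltage-gated channels (0.0101) and ribosomal proteins (0.0206) gained, and with the GC offset the noradrenergic factors (0.0287) and ribosomal proteins (0.0486) gained. Without a library in turn, the voltage-gated channels ranged from 0.0495 (without undifferentiated replicate 2) to 0.0588. The uncalled list of mitochondrially encoded genes changed direction with DESeq2 (0.622), limma voom (0.862), fry (0.92), without undifferentiated replicate 2 (0.988) and without dexamethasone replicate 1 (0.932); without a library in turn it ranged from 0.751 to 0.988. Of the 162 genes named by the rule none changed direction under the alternatives run on them. Acadm and Foxa1 lost their call in 4 and 2 of the 6 runs without a library, and under other alternatives Acadm, Pmp22, Atg5 and Foxa1 lost theirs and Cdkn1c gained one with limma voom. Depth limits what can be said of genes such as Slc6a2, Slc18a2, Pnmt and Nefl, which had at most 7 reads in a group.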

Other observations

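The lists and families in these first paragraphs, the tests of the Xist pattern, the count of interferon reads and the run without processed pseudogenes were chosen after the gene values had been seen; the test of other splits and both tests of the pseudogenes were set before their results were seen. Lists of known targets of 3 regulators were written after some of their members had been seen among the larger changes, so their counts are not independent evidence of a direction; their p-values were adjusted over these and the imprinted genes. Of 21 tested FOXO targets 20 rose and 1 fell (median log2 fold change 1.62, camera adjusted p = 1.5e-13, and 0.019 with an estimated correlation), and 12 of these genes are also on the fixed lists. Klhl24, a ubiquitin ligase adaptor, rose 4.93-fold and Sesn3, a stress-induced inhibitor of mTORC1, 2.89-fold. Of 30 tested ATF4 targets 26 rose and 3 fell (median 1.19, camera adjusted p = 5.92e-15, and 0.019 with an estimated correlation), with 10 on the fixed lists. The transcription factor gene Atf5 rose 10.4-fold and Nupr1 56.5-fold, while Psat1 of serine synthesis fell 1.76-fold. Of 12 tested LXR targets 11 rose and 1 fell (median 1.23, camera adjusted p = 6.35e-07, and 0.019 with an estimated correlation), with 4 on the fixed lists. Abca1, which exports cholesterol, rose from 3.24 to 149 CPM (means of n = 3; log2 fold change 5.52 ± 0.112 SE). Imprinted genes, 22 tested, rose in 11 and fell in 7 cases and were not called (camera adjusted p = 0.994). These directions were the same with RLE factors, upper quartile factors and library totals. Such scalings shift all genes by nearly the same small amount, so this check could hardly come out otherwise.

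Among 117 families of coding genes that share a symbol prefix, each with at least 10 tested members, 31 were called with camera's preset correlation, 9 up and 22 down. With an estimated correlation camera called 0, and 16 had an unadjusted p under 0.05; fry, DESeq2 and limma voom were not run on families. All 17 tested Pcdhb genes, the clustered beta protocadherins on chromosome 18, rose (median log2 fold change 2.18, adjusted p = 0.0297; adjusted p = 0.51 with an estimated correlation). Pcdhb17 rose from 4.44 to 20.8 CPM, though reads of these similar genes can be split between copies. Of 13 semaphorin genes 12 rose and 1 fell (median 1.41, adjusted p = 0.0297; adjusted p = 0.31 with an estimated correlation). Of 18 genes with the prefix Nup, mostly nucleoporins, 17 fell and none rose (median -1.07, adjusted p = 4.83e-08; adjusted p = 0.27 with an estimated correlation). Of 10 Srsf splicing factor genes 9 fell and 1 rose (median -1.39, adjusted p = 1.27e-07; adjusted p = 0.28 with an estimated correlation), Srsf2 from 652 to 143 CPM. All 13 Psmd proteasome genes fell (median -0.77, adjusted p = 0.000834; adjusted p = 0.35 with an estimated correlation), and so did 42 of 48 Mrpl genes of the mitochondrial ribosome, with 1 higher (median -0.55, adjusted p = 0.00149; adjusted p = 0.28 with an estimated correlation). The medians of these families kept their sign under the 3 other scalings. Those scalings moved the median of all tested genes from 0.02 to 0.01, 0.12 and 0.14, less than the size of these family medians. A change of sign was therefore not to be expected, and the check adds little.

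With 3 libraries against 3 there are 10 splits of the libraries, too few for a share under 0.1. The real split, 1 of these 10, called 9997 genes with edgeR. The highest of the other splits called 0 at an adjusted p under 0.05, and at most 28 genes had an unadjusted p under 0.05. No other tool was run on the splits. Each other split put libraries of both groups on both sides, so the group difference added to the spread it was tested against. Few or no calls were therefore likely from the outset, and these splits cannot tell whether the 9997 calls exceed chance.

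Processed pseudogenes, copies of mature mRNAs without introns, were lower more often than higher in differentiated cells, with 301 lower and 53 higher of 613 tested (median log2 fold change -0.47). Among the 307 pseudogenes at or above the median abundance of 4.02 CPM, 186 were lower and 30 higher (exact two-sided binomial p = 1.11e-28). These counts argue against low counts alone, for pseudogenes of that abundance. The binomial test and the shufflings below take pseudogenes as independent, which copies of the same gene are not. The binomial p may therefore be far too small. Of 328 called pseudogenes whose best coding match was also called, 98.8% had the direction of that match, while 1000 shufflings of the matches gave at most 81.7%. The median identity of the matches was 98.0%, so reads of parent genes counted at their pseudogenes are a candidate explanation. Leaving these pseudogenes out gave 4969 higher and 4721 lower genes, and whether any of the pseudogenes is itself transcribed was not tested.

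Xist, the RNA that coats the inactive X chromosome, was counted at 399 to 496 CPM in all 6 libraries, although the labels give the line's sex as male, and it did not differ detectably between groups (log2 fold change 0.01 ± 0.059 SE, edgeR adjusted p = 0.891). Reads of the antisense gene Tsix are argued against as its source, since Tsix had at most 0.0246% of the Xist reads in a library. The Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty had 0 reads against 35451 of their X-linked copies (a share of 0% in every library, and up to 0.00846% over all from a floor of 3 reads), which argues against cells that carry and express an intact Y chromosome. Other Y genes had 376 reads, 336 of them at Gm47283, 38 at Mid1-ps1 and 2 at Gapdh-ps15, and whether these came from a retained part of the Y or from similar sequence elsewhere was not tested. A line of female origin may account for the Xist and Y-linked counts. So may a Y chromosome lost in whole or in part in culture, with more than 1 X chromosome. These explanations cannot be separated with counts, and neither was tested, since the design has no group that differs in sex.

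All 17 tested interferon-response genes rose. All 17 were also called higher with RLE factors, upper quartile factors and library totals, with list medians of 1.57, 1.68 and 1.70. Since these scalings shift all genes by nearly the same small amount, that adds little evidence. The 21 interferon genes had 1 read in undifferentiated and 1 read in differentiated libraries, so interferon made by the cells was not detectable at this depth and stays open. The change of serum and the steroid, which differ together between the groups, stay open as untested causes. The call of the list itself was lost with an estimated correlation (adjusted p = 0.19).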
